A study of Actinidia chinensis with 2 samples.

How the data were processed

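The data are single-cell RNA counts from leaves of kiwifruit (Actinidia chinensis cultivar Hongyang). There were 2 libraries, 1 from the wild type and 1 from a transgenic line of AaBAM3.1. BAM is the usual abbreviation for beta-amylase, an enzyme that releases maltose from starch, and the labels do not say how the transgene alters its level. Per the labels' protocols, single cells were loaded on the 10x Chromium system, in which each droplet tags the polyadenylated RNA of a cell with a barcode and each molecule with a unique molecular identifier (UMI), and libraries were made with the Single Cell 3' v3 chemistry.

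The deposited matrices hold raw UMI counts per gene and barcode, as whole numbers with no normalization. Per the file headers, the authors made them with Cell Ranger 5.0.0, and the submitters' processing notes also name STAR, the aligner. The genome build and annotation are not given in the sources used here. Both libraries share an identical list of 40494 features. Of these, 40466 carry only an Actinidia number and no gene name. The other 28 carry the names of organelle ribosomal RNA and transfer RNA genes. No gene annotation was used here, so none of the 23 lists of leaf cell type markers and functional genes fixed in advance could be matched to a nuclear gene. These lists covered mesophyll, epidermis, guard cells, trichomes, phloem, xylem, procambium, bundle sheath, dividing cells, S-phase cells and meristem. They also covered beta-amylases, starch breakdown and synthesis, sugar transport, cold response, antioxidants, flavonoids, wounding, heat shock, ribosomal proteins, housekeeping genes and transgene sequences. The AaBAM3.1 transgene itself was not analysed here for the same reason. Clusters of cells are therefore given by number and not by cell type.

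The deposited barcode lists held exactly 10000 wild-type and 15000 transgenic barcodes, and 46 barcode sequences occurred in both. Barcodes with at least 500 UMIs, at least 300 detected features and at most 10% of UMIs from mitochondrial ribosomal RNA were kept. The files do not state from which organelle each feature comes. By the usual naming, rrn5, rrn18 and rrn26 were taken as mitochondrial for this filter and rrn16 was not counted. The filter left out 438 wild-type barcodes and 1 transgenic barcode and kept 9562 and 14999 cells. No barcode was under 500 UMIs. In the wild-type library 44 barcodes were under 300 features and 410 were above the limit of 10%. Doublets were searched for in each library with Scrublet (scanpy 1.11.5, expected rate 0.06, automatic threshold). It called 0 barcodes in each library, so no barcode was removed as a doublet and any doublets remain in the results. The number of doublets was not measured. An alternative removed the 8% of barcodes with the highest Scrublet scores.

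Cells of both libraries were clustered together with Seurat 5.3.0 in R 4.3.3. Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 variable features and 30 principal components were used, the libraries were integrated by reciprocal PCA, and Louvain clustering was run at resolution 0.5. Features seen in fewer than 3 cells were left out of this step. On 4 simulated cell types in 2 libraries with shifted gene levels, the same code returned 4 clusters with integration and 8 without it, and 100% of the cells lay in a cluster of their own type in both cases. The simulated types had unrelated profiles, equal expected shares and depth in both libraries, and gene shifts common to all types. The check therefore does not show whether similar cell types are kept apart or rightly matched in the real data.

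UMIs of each feature were summed over the kept cells of a library and expressed as CPM, the share of that sum scaled to 1e+06. The ratio of transgenic to wild-type CPM was given an exact conditional binomial 95% interval. Genes were compared where they had at least 100 UMIs over both libraries and at least 20 CPM in 1 of them, and the number with a ratio of at least 2 in either direction was counted. Within clusters, the same ratio was taken in each cluster with at least 100 cells of each library, with 0.5 added to each sum, and summarized by the median over clusters. Shares of cells have exact (Clopper-Pearson) 95% binomial intervals. All intervals cover counting error only. There is 1 library per genotype, so there is no replicate, no test between genotypes and no p-value, and each difference is a difference between these 2 libraries. On simulated sums for the transgenic against wild-type comparison with 6884 genes compared, 100% of the genes changed 3-fold in either direction and 0% of the genes changed 1.5-fold were counted as 2-fold different. Of the 6700 unchanged genes, 0% were counted and the interval held the true ratio for 95.6%. For the sets of changed genes the interval held it for 88% to 97.7%. The sums were simulated with counting spread alone, which is what the interval assumes. The check therefore tests the code, and not how the interval covers the uneven spread of real UMIs over cells.

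The difference in the makeup of the libraries is given as the dissimilarity, the percentage of cells of a library that would have to change cluster to match the shares of the other. The main choices, the alternatives and the rule for named genes were fixed before the data were examined. That rule took, where no names exist, the 2 identifiers with the largest ratio and the 2 with the smallest among genes that were at least 2-fold different and went the same way in at least 9 of the 11 clusters compared. The alternatives fixed in this way were a stricter cell filter, other doublet settings, no integration, other resolutions and dimensions, TMM scaling (edgeR 4.0.16), other count minimums, cells thinned to 500 UMIs and equal weights for clusters. Alternatives added after seeing the data were a UMI minimum of 1426 in both libraries, a 10% limit on all 28 organelle features, clustering without those features, clustering without 4265 features that differed at least 2-fold over all cells (taken over all features with 1 added to each CPM and no count minimum, so they outnumber the differing genes of the main comparison), CPM without organelle features, and sums without cluster 3.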

Results

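Leaf cells of Hongyang kiwifruit and of a transgenic line of AaBAM3.1 in the same cultivar were profiled to build an atlas of leaf cells and to compare both genotypes. Each genotype is represented by 1 library. The wild-type library held 16550005 UMIs in 10000 barcodes and the transgenic library 33436662 UMIs in 15000 barcodes. The kept wild-type cells had a median of 1283 UMIs and 750 detected features, and the kept transgenic cells a median of 1933 UMIs and 1111 features. The lowest barcode had 715 UMIs in the wild type and 1426 in the transgenic library, so 5783 of the deposited wild-type barcodes (57.8%) lay below the shallowest transgenic barcode. Both barcode lists have a round length. The lowest counts, the UMI totals and the medians depend on where each list ends. After each cell was thinned to 500 UMIs, with no cell left out, the median was 350 features in the wild type and 368 in the transgenic library, and with only cells of at least 1426 UMIs it was 355 and 368.

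**Figure D1:**
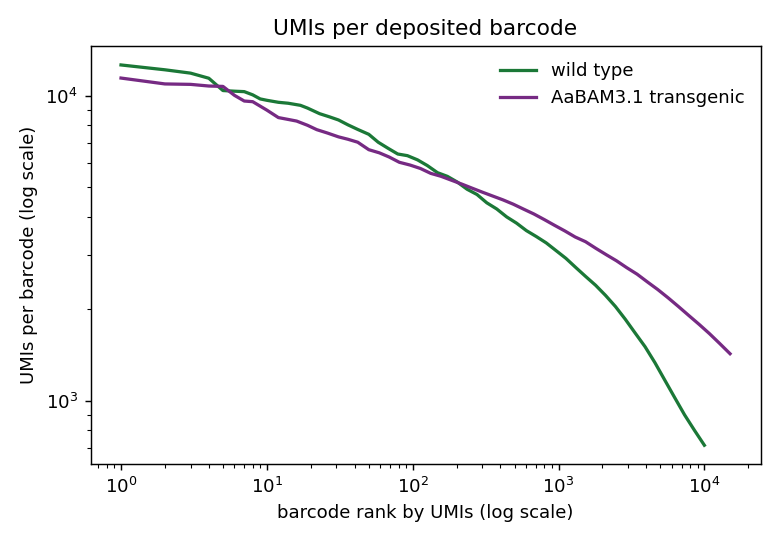
UMIs per deposited barcode (vertical axis, log scale) against the rank of the barcode within its library (horizontal axis, log scale), with 1 line per library. The lines end at 715 UMIs for the 10000 wild-type barcodes and at 1426 UMIs for the 15000 transgenic barcodes.

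The named features of the files are organelle RNAs, and they took a larger share of the wild-type library. Ribosomal RNA rrn16, whose name is that of the plastid small-subunit ribosomal RNA, made up 6.95% of the UMIs of kept wild-type cells (95% interval 6.94 to 6.96) and 2.74% in the transgenic library (2.73 to 2.75), a 2.54-fold difference. The rrn26 feature, named as the mitochondrial large-subunit ribosomal RNA, made up 2.18% (2.17 to 2.18) and 1.18% (1.18 to 1.18). The rrn18 feature, named as the mitochondrial small-subunit ribosomal RNA, made up 0.204% (0.202 to 0.206) and 0.0495% (0.0488 to 0.0503), a 4.12-fold difference. The rrn5 feature made up 0.00724% and 0.00342%. The cell filter limited rrn5, rrn18 and rrn26 themselves. Over all deposited barcodes the difference was 2.04-fold for rrn26, against 1.85-fold in kept cells, and 4.56-fold for rrn18. The transfer RNA features together held 182 UMIs in the wild type and 146 in the transgenic library. All 28 organelle features together made up 9.34% of the wild-type and 3.97% of the transgenic UMIs.

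The median share of organelle RNA per cell was higher in the wild type in 11 of the 11 clusters with at least 100 cells of each library. In cluster 1, the largest, it was 17.7% in the wild type and 5.69% in the transgenic library, and in cluster 4 it was 4.90% and 2.29%. The share fell with depth within each library. In cells of 1426 to 1630 UMIs the median was 8.64% in 727 wild-type cells and 4.14% in 3742 transgenic cells. In cells of 1933 to 2524 UMIs it was 6.50% and 3.29%. In the deepest twelfth of each library, with a median of 4149 and 4170 UMIs per cell, it was 2.44% and 2.13%. Restricting the wild type to the 4206 cells of at least 1426 UMIs lowered its rrn26 share to 1.38%, 1.17-fold that of the transgenic library, its rrn16 share to 4.89%, 1.78-fold, and its rrn18 share to 0.125%, 2.52-fold.

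**Figure D2:**
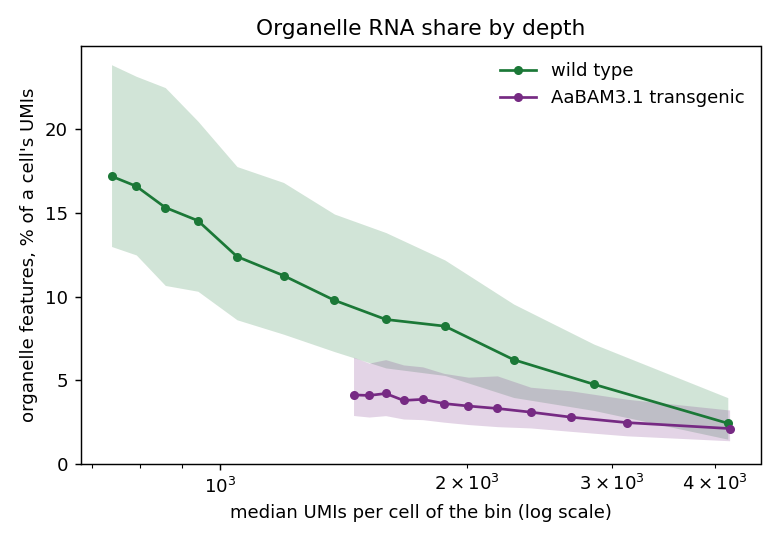
Share of a cell's UMIs from the 28 organelle features (vertical axis, percent) against the median UMIs per cell (horizontal axis, log scale), in 12 bins of equal cell number per library. Points are medians and bands run from the lower to the upper quartile of cells. The wild-type median falls from 17.2% to 2.44% and the transgenic median from 4.14% to 2.13%.

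Over all cells, 7736 genes were compared between the libraries. Of these, 989 (12.8%) were at least 2-fold higher in the transgenic library and 911 (11.8%) at least 2-fold lower. The whole counting interval lay beyond 2-fold for 790 of the higher and 707 of the lower genes. A 4-fold difference was reached by 284 higher and 160 lower genes, and a 10-fold difference by 45 higher and 22 lower genes. The median log2 ratio was -0.09, with quartiles of -0.61 and 0.51. When the cells of a library were divided at random into equal parts, 1 of 6874 genes differed 2-fold in the wild type and 0 of 6816 in the transgenic library. This is the spread from counting and from sampling of cells, and the spread between plants or between library preparations was not measured. With organelle features left out of the CPM, 874 genes were higher and 1068 lower, and with each cell thinned to 500 UMIs 857 were higher and 874 lower, so the balance between the directions turned in both.

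**Figure D3:**
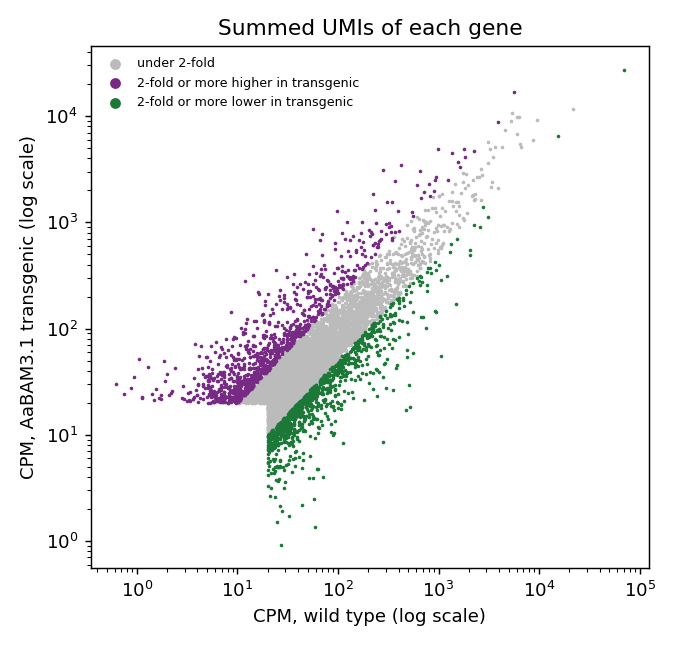
CPM of each of the 7736 genes compared, in the wild-type (horizontal axis, log scale) and the transgenic library (vertical axis, log scale), with 1 point per gene from sums over kept cells. Purple points mark the 989 genes at least 2-fold higher in the transgenic library and green points the 911 genes at least 2-fold lower.

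The genes that differed over all cells mostly went the same way within clusters. A gene was counted as higher or lower in a cluster at any size of ratio. The sums over all cells hold the cells of these clusters, so this is not independent support. Of the 989 higher genes, 970 were higher in at least 9 of the 11 clusters compared and 676 in all 11 of them. Of the 911 lower genes, 840 were lower in at least 9 clusters and 504 in all 11. By the median over clusters, 926 genes were at least 2-fold higher and 645 at least 2-fold lower, and 835 and 607 of these were among the genes that differed over all cells. Where a gene had no UMIs of either library in a cluster, the 0.5 added to each sum put the library with the larger UMI total lower, which was the transgenic library in 8 of the 11 clusters. Clusters of a library share its preparation and its free RNA, so they are not independent of each other.

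The share of genes that differed 2-fold was highest in cluster 3. There 1154 genes were at least 2-fold higher and 1424 lower in the transgenic cells, 36.0% of the 7153 genes compared in that cluster, and the interval lay beyond 2-fold for 744 and 782 of them, 21.3%. In clusters 10 and 11 the shares were 33.7% of 2611 and 32.3% of 1835 genes, with the interval beyond 2-fold for 16.3% and 17.3%. Cluster 9, with 102 wild-type cells, had 32.6% of 3642 genes by the ratio but 7.39% by the interval, the lowest of the 11 clusters. Cluster 5 had the lowest share by the ratio, 21.1% of 4396 genes, and 11.4% by the interval, cluster 1 had 22.2% of 7494 genes and 11.1%, and cluster 4 had 24.9% of 6855 genes and 13.5%. Of the 10 leading genes, 10 differed 2-fold in cluster 3 (with 0 shared by the lists of each library alone), 10 in cluster 5, 6 in cluster 10 and 7 in cluster 11, and the wild-type profiles of clusters 3 and 9 were closest to transgenic clusters 2 and 5, so the cells compared under these numbers are not shown to be the same. The number of genes that could be compared rose with the UMIs of a cluster, so these shares are not over the same genes.

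The files pair the nuclear identifiers with no gene names, and 4 identifiers were picked by size. Actinidia06826 was higher in the transgenic library, at 51.5 CPM against 1.05 in the wild type, a ratio of 48.9 (95% interval 30.4 to 84.1). It was higher in 11 of 11 clusters, but it had 17 wild-type UMIs in all and 0 CPM in wild-type cluster 2. Its ratios within clusters thus rest on few UMIs or on the 0.5 added to each sum. Of its transgenic UMIs, 32.7% came from cluster 7, and 50.3% came from all clusters outside the 11 compared. With the 11 compared clusters weighted equally, which leaves the other clusters out, the ratio was 11.0. This weighting also leans on wild-type cluster 10, with 177 cells, which held 29.4% of the 17 wild-type UMIs, at 18.5 CPM. Actinidia23105 stood at 29.8 CPM against 0.619, a ratio of 48.1 (26.0 to 100.6) from 10 wild-type UMIs, and was higher in 10 of 11 clusters. No cluster held over 20% of these 10 UMIs, and wild-type cluster 6 had 0 CPM. Its ratios within clusters thus also rest on few UMIs or on the added 0.5. Cluster 14, with 1.91% of the transgenic cells, held 75.5% of its transgenic UMIs, at 1001 CPM. The ratio of Actinidia23105 was 21.5 with the compared clusters weighted equally, which leaves out clusters with 78.6% of its transgenic UMIs. It was 31.9 in cells thinned to 500 UMIs.

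Of the 2 identifiers picked as lower, Actinidia29093 was at 1.35 CPM in the transgenic library and 59.3 in the wild type, 44.0-fold lower (32.6 to 60.8). Actinidia15429 was at 8.52 and 281.4 CPM, a ratio of 0.0303 (0.0268 to 0.0341). Both were lower in 11 of 11 clusters, of which the choice required at least 9. Cluster 3 held 52.5% of the wild-type UMIs of Actinidia29093 and 62.8% of those of Actinidia15429. With the clusters weighted equally Actinidia29093 was 28.3-fold lower and the ratio of Actinidia15429 was 0.0462. Without cluster 3 the latter ratio was 0.0510.

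The kept cells formed 16 clusters of 26 to 5026 cells. Cell types were not assigned because no marker could be matched. For 11 clusters with at least 100 cells of each library, the profile summed within a library was compared with the other clusters of that library. In both libraries cluster 1 was nearest to cluster 6 (Pearson r = 0.92 and 0.97 across genes, which are not independent replicates), and clusters 2, 3 and 8 formed a chain in which 8 was the nearest neighbour of 2 and of 3. Cluster 4 was nearest to cluster 3 in both. The nearest neighbour was the same in both libraries for 7 of 11 clusters, while random relabelling of the clusters gave a median of 1, and as many in 0.02% of 10000 relabellings. Clusters 5, 10, 11 and 12 had different nearest neighbours in the libraries. Among the transgenic clusters only, the wild-type profile was closest to that of the same number for 7 of the 11 clusters. Wild-type clusters 3, 6, 8 and 9 were closest to transgenic clusters 2, 1, 2 and 5. The r between clusters of the same number was 0.74 to 0.87. In each of the 11 it was below the r with the nearest other wild-type cluster. Each wild-type cluster was thus more like another cluster of its own library than its transgenic counterpart. The clusters were aligned by integration, so the match is not independent of the method, and no direction of development was assigned because no starting cell type could be set.

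Sizes are given for the 5 clusters in which at most 3 of the 10 leading genes, taken over both libraries, differed 2-fold within the cluster, a limit chosen after the data were seen. These 5 held 52.3% of the wild-type and 57.9% of the transgenic cells, and the other 11 clusters the rest. The leading genes taken in each library alone agreed less, with 5 of 10 shared in cluster 1, 3 in cluster 2, 4 in cluster 4, 3 in cluster 6 and 3 in cluster 9. Cluster 1 had 0 genes at least 4-fold over the rest in either library, and cluster 6 had 56 in the wild type and 0 in the transgenic library. Clusters 6 and 9 are among those whose wild-type profile was closest to another transgenic cluster, so the match of cells behind their sizes was not established. Cluster 1 held 19.8% of the wild-type cells (95% interval 19.0 to 20.6) and 20.9% of the transgenic cells (20.2 to 21.6), with overlapping intervals. Cluster 2 held 12.3% (11.6 to 13.0) and 16.3% (15.7 to 16.9), and cluster 6 held 7.60% (7.08 to 8.15) and 8.81% (8.36 to 9.28). Cluster 4 held 11.6% (11.0 to 12.3) of the wild-type and 6.55% (6.16 to 6.96) of the transgenic cells. Cluster 9 held 1.07% (0.871 to 1.29) and 5.39% (5.04 to 5.77). The UMI minimum moved these shares. Among cells of at least 1426 UMIs, cluster 1 held 6.56% of the wild-type cells, cluster 2 held 11.8%, cluster 6 held 6.73%, cluster 4 held 21.9% and cluster 9 held 0.333%, and the transgenic shares were as before. The order between the libraries was the same for these 5 at either minimum. Among the other compared clusters, which did not meet the limit on leading genes, it turned for cluster 5, from 15.3% of the wild-type and 3.93% of the transgenic cells to 2.07% and 3.93%, and for cluster 11, from 3.65% and 2.22% to 1.45% and 2.22%. The dissimilarity over all 16 clusters was 33.1%.

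When cells were grouped without the 4265 features that differed 2-fold (of all features, with 1 CPM added and no count minimum), 10 groups were found and the dissimilarity was 17.6%. The features were chosen on these same libraries, so they can include genes of cell types with unequal shares. The number of clusters also fell, from 16 with a dissimilarity of 33.1%. With all features, the lower resolution gave 28.4% in 11 clusters and the higher resolution 39.7% in 19. The lower value therefore does not measure the difference in makeup apart from differences in expression. Group 1 held 29.0% of the wild-type cells (28.1 to 29.9) and 31.4% of the transgenic cells (30.7 to 32.2), and 14.3% of the wild-type cells of at least 1426 UMIs. Group 2 held 13.7% (13.1 to 14.4) and 24.0% (23.3 to 24.7), and group 5 held 10.2% (9.61 to 10.8) and 6.52% (6.13 to 6.93). At that minimum the wild-type shares were 14.0% for group 2 and 19.0% for group 5. Group 4 held 16.1% (15.4 to 16.8) of the wild-type cells and 10.3% (9.82 to 10.8) of the transgenic cells, but 2.64% of the wild-type cells of at least 1426 UMIs, so its order turned with the UMI minimum. Group 7 turned as well, from 3.22% against 2.33% to 1.74% against 2.33%. Group 3 held 22.6% of the wild-type and 16.0% of the transgenic cells, and 44.1% of the wild-type cells of at least 1426 UMIs. Group 8 held 1.66% (1.42 to 1.94) and 1.11% (0.946 to 1.29), and 1.81% of the wild-type cells of at least 1426 UMIs. Groups 3 and 7 did not meet the limit on leading genes, with 10 and 5 of 10 differing 2-fold, and groups 1, 2, 4, 5 and 8 met it. The leading genes taken in each library alone shared 1 of 10 in group 1, 4 in group 2, 0 in group 3, 2 in group 4, 4 in group 5, 2 in group 7 and 7 in group 8. Group profiles were not matched across the libraries, so for none of these groups are the sizes shown to be of the same cells.

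**Figure D4:**
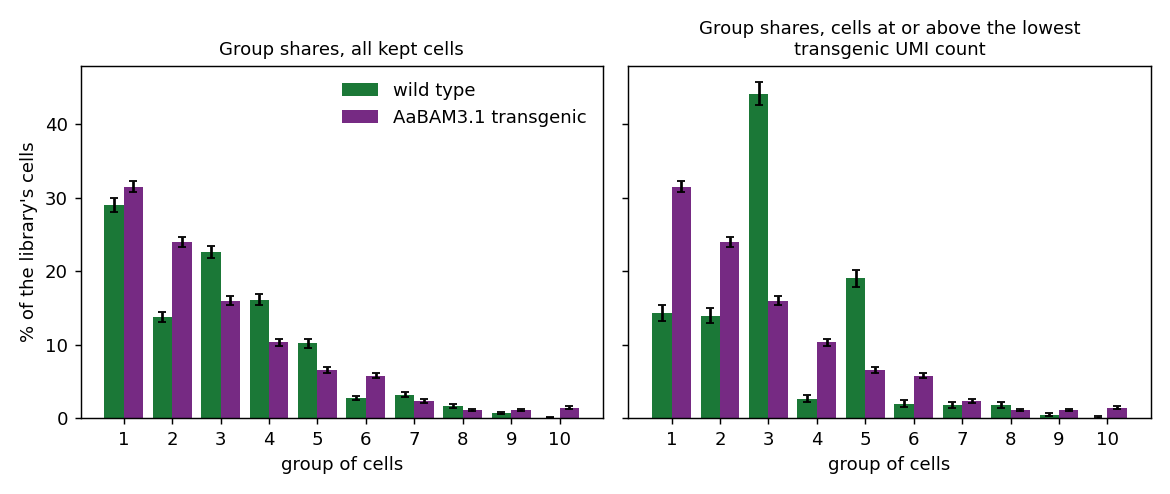
Share of the cells of each library (vertical axis, percent) in each of the 10 groups (horizontal axis) found without the features that differed 2-fold, for all kept cells (left) and for cells of at least 1426 UMIs (right). Bars start at 0 and error lines are exact 95% binomial intervals for counting error. Wild-type group 4 drops from 16.1% to 2.64% and group 3 rises from 22.6% to 44.1% between the panels.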

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

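Without integration the dissimilarity of the libraries was 97.7%, and 1 cluster had enough cells of both libraries, in which 1344 genes were at least 2-fold lower. The other cluster settings gave 31.4% with minimums of 1000 UMIs and 500 features, 35.2% with the 8% highest Scrublet scores removed, 28.4% at resolution 0.3, 39.7% at resolution 0.8 and 28.8% with 20 dimensions. Settings added after the data were seen gave 42.8% with a minimum of 1426 UMIs in both libraries, 35.4% with at most 10% organelle UMIs, and 17.6% in 10 clusters without the genes that differ 2-fold. The last grouping moved the number of clusters by more than 1.5 times, and the other 10 settings gave 11 to 19 clusters. The number of kept cells was 6307 in the wild type with the stricter minimums, 8797 and 13799 without the highest Scrublet scores, 4206 in the wild type with 1426 UMIs, and 4568 and 14251 with the organelle limit. Thinning to 500 UMIs lowered the median features per cell to 350 and 368. Over all cells, 11 of 12 alternatives gave 780 to 1370 genes higher and 736 to 1120 lower. With no minimum beyond 1 UMI there were 7873 and 5622 of 33067 genes, since genes of a few UMIs differ 2-fold by counting alone. Within clusters that setting gave 2537 higher and 6812 lower, because 0.5 added to empty sums puts the larger transgenic totals lower. The other alternatives gave 900 to 1176 higher, with 967 in the run without integration, and 619 to 950 lower, apart from the 1344 of that run. None of the ratios of the 4 named identifiers changed direction under the alternatives in which it was computed. These identifiers were picked for the size of their ratios and for the same direction within clusters. The alternatives reuse the same cells, so this is not independent support. Leaving Scrublet calls in changed nothing because there were none. The alternatives for gene lists were not run because no list matched. With 1 library per genotype no library could be left out, and no replicate error could be had.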

Other observations

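All tests of the organelle pattern were chosen after it was seen. The test of shallow barcodes against their own sum was also chosen after related results were seen, and the other tests were set before their results were known. Some clusters were mostly of the transgenic library. Cluster 14 had 286 transgenic and 8 wild-type cells, cluster 13 had 308 and 40, cluster 7 had 1544 and 91, and cluster 9 had 809 and 102. In these clusters 7, 5, 8 and 3 of the 10 leading genes differed 2-fold between the libraries, so a cluster of this kind can be the library and not a cell type. Cluster 14 had 129 genes at least 4-fold above the rest of the transgenic cells, and cluster 7 had 2. Clusters 1 and 8 had 0 such genes in both libraries. The ratio of rrn16 to rrn26 UMIs was 3.19 in the wild type and 2.32 in the transgenic library, and 3.53 in wild-type cells of at least 1426 UMIs, so these RNAs did not differ by the same factor.

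Within the wild type, cells under 1426 UMIs differed 2-fold from deeper cells for 1215 genes that were higher and 446 that were lower in the shallow cells, 21.6% of 7695 genes. This is close to the 24.6% of genes that differed between the libraries. Setting the minimum to 1426 UMIs in both libraries did not lower the difference between them, with 1370 genes higher and 1120 lower. This minimum also changed the makeup of the wild type. Cluster 3 rose from 20.9% to 40.1% of its cells, and cluster 1 fell from 19.8% to 6.56%. Shallow and deep wild-type cells thus differ in clusters as well, so neither comparison shows the part of depth alone.

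The libraries fell apart without integration, with a dissimilarity of 97.7%. A difference in UMIs per barcode as the whole cause is argued against. The dissimilarity was 97.0% after every cell of at least 1426 UMIs was thinned to 1426. Organelle RNA as the whole cause is argued against, since the dissimilarity was 97.5% without the 28 features. With values this near 100%, a part of either in the separation stays open. A few genes that differ strongly were not tested by themselves. Without the 4265 features that differ at least 2-fold it was 84.8%, between the limits of 50% and 90% set in advance. These features are many, most need not differ strongly, and they were chosen on the same libraries. They include the genes that differ strongly over all cells, and much of the separation stayed without them. By the limits set in advance this result is undecided. The part of such genes in the separation stays open. Genotype and library preparation or plant apart from genotype cannot be told apart with 1 library per genotype.

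The organelle RNA share was higher in the wild type. A difference in UMIs per barcode as the whole cause is argued against for cells of 1426 to 2524 UMIs, where the lowest ratio of the medians over 3 bins was 1.97, although the deepest cells of the libraries nearly met at 2.44% and 2.13%. Different sizes of the numbered clusters as the whole cause are argued against, since the wild type was higher in 11 of 11 clusters. These medians were not matched for depth. Wild-type cells were shallower in cluster 1 (medians of 925.5 and 1710 UMIs) and in most other compared clusters, but deeper in cluster 8 (2630 and 2172.5). Cells under 1 cluster number are not shown to be the same, so a different makeup of cell types stays open. Cell damage during preparation, the handling of each library and the genotype stay open and were not tested.

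Of the 9562 kept wild-type cells, 5356 (56.0%) were shallower than any transgenic cell, and both barcode lists had a round length. Droplets that hold only free RNA could not be excluded. The likelihood of these barcodes under the summed profile of their library lay inside the central 95% of simulated draws for 34.6% of them (95% interval 33.3 to 35.9), and for 21.2% of deeper wild-type cells and 35.6% of transgenic cells. This is under the limit of 50% set in advance, but that limit was wrong to use, since it assumed that free RNA follows the library sum and varies between droplets by counting alone, and neither was measured. Their own sum would be the profile if every one were a draw from 1 free RNA profile. Under it, 30.8% of them (29.5 to 32.0) lay inside with all features and 34.5% (33.2 to 35.8) without organelle features. Simulated draws gave 94.2% and 94.0%. This argues against every one of the 5356 being a draw from 1 fixed profile with counting spread alone. Free RNA in some of these barcodes, or with more spread between droplets, stays open, since that spread was not measured. No biological explanation was tested.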
